A study of Mus musculus with 9 samples.

How the data were processed

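Total RNA of tomato-positive cells from pools of animals was amplified, labelled with biotin and hybridised to Illumina BeadChips, 1 array per pool, as the labels describe; the 9 arrays fall into 3 groups of 3 pools. The deposited table of non-normalised values gives the bead-summarised intensity of each probe on a linear scale, exported by the authors from GenomeStudio (version not given) without background subtraction or normalisation. The deposited table also gives a detection p-value per probe and array, computed in GenomeStudio against the negative controls of the array, in steps of 1/798. The deposited value table holds linear intensities that were quantile-normalised between arrays before deposition; its column medians lie between 198 and 199 and each column ranks the probes as the raw column of the same array does. No control probes, bead counts or slide positions are in the files.

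The non-normalised intensities were background-corrected by normexp convolution with control statistics inferred from the detection p-values, offset by 16, quantile-normalised and log2-transformed (neqc method, limma 3.58.1, R 4.3.3). Of 25697 probes 23978 carried 1 gene symbol in the platform annotation and 1719 (6.69%) carried none. Probes with a detection p under 0.05 on at least 3 of the 9 arrays were kept, which left 14519, of which 858 had no symbol. For each gene the probe with the highest mean over all arrays was used, which gave 10073 genes. Probe positions in the genome are not given, since the files name no genome build.

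A linear model with 1 mean per group was fitted to all 9 arrays with limma (lmFit, contrasts.fit and eBayes, 6 residual degrees of freedom), each pair of groups was contrasted with a two-sided moderated test, and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene passed, and is said to rise or fall, at an adjusted p under 0.05. Standard errors are those of the moderated fit. The test was tried once per comparison on simulated values for 9 arrays in the same groups, with 200 of 10073 genes changed. The noise was drawn independently for each gene around its mean, with its moderated spread. It held no correlation between genes and no arrays that stand apart, so the shares below need not hold for the real arrays. For day 6 against unfractured it found 1.49% of changes of 2-fold, 59.7% of 4-fold and 83.3% of 8-fold, with 4.95% false among those found. For day 2 against unfractured the shares were 7.46%, 67.2% and 87.9%, and 4.42% were false.

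A gene whose probes were all undetected on the 3 arrays of a group has a fold change that depends on the offset. For such genes the text gives a lower bound, the mean of the other group over the intensity at which probes are detected on the arrays of the undetected group. No bound and no fold is given where both groups were undetected.

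Lists of genes for 25 pathways or tissues and 11 cell types were written before the data were examined, as were the groups, the tests, the alternatives and the rule for the genes named. Of these, 34 lists had at least 5 measured genes and were tested with camera in limma, two-sided, with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the lists. Camera asks whether the genes of a list moved relative to the other genes. An alternative estimated the correlation from the data, which in a design of 9 arrays leaves 6 residual degrees of freedom. The genes named are, per comparison, the 10 largest rises and the 10 largest falls among genes that passed and whose groups did not overlap, up to 4 members of each list by adjusted p, and a fixed panel of 29 genes; from the panel Runx2, Spp1, Mki67, Ly6a and Bmp2 were not measured. Genes named within a list whose call rests on the 6 arrays were taken from the same selection.

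The labels do not say that a replicate number pairs pools. The correlation of deviations from group means between arrays of the same number ran from -0.31 to 0.40 for unfractured and day 2 and from -0.28 to 0.26 for unfractured and day 6. These values cannot tell whether the numbers pair those pools. The leukocyte-rich array is number 3 in the unfractured group and number 1 in both fracture groups, while number 2, without such an array, gave 0.40 and 0.26. For day 2 and day 6 the correlation was 0.51 to 0.63 in all 3 pairs. For that comparison the block for replicate number, fitted over all 9 arrays, is therefore given beside each call that it ends. That fit also places the unfractured pools in the blocks. A call that it ends need not end in a test of the day 2 and day 6 pairs alone, which was not run. The pairing of day 2 and day 6 pools comes from the values alone: pools of number 1 are leukocyte-rich in both groups, and pools of numbers 2 and 3 correlated across numbers at 0.33 and 0.57. Replicates of a group correlated at 0.854 to 0.990 across genes, and no pair of arrays shared identical columns. Alternatives were quantile normalisation without background correction, scaling to a common median, the deposited value table, no detection filter and a stricter one, all probes, stricter thresholds, a fit of only the groups compared, sex in the model, replicate number as a block, array weights estimated or set by the number of animals pooled, trended and robust moderation, and leaving out each array in turn. After the values were seen, 3 more were added: leaving out the 3 arrays rich in leukocyte transcripts (those whose mean log2 value of 35 macrophage and pan-leukocyte genes lay above 9), a block for those arrays, and the marker mean as a covariate. Sex was tested with group in the model, and its interaction with group with an F test in limma. Slide could not be used as a block because the files do not give it.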

Results

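Gene expression was measured with bead arrays in tomato-positive cells sorted from the tibial periosteum of αSMACreERT2/Ai9 mice. In these mice the promoter of alpha smooth muscle actin drives a Cre recombinase that tamoxifen activates, and the Ai9 reporter marks the recombined cells and their descendants with the red fluorescent protein tomato. The 9 arrays held 3 pools of unfractured periosteum, 3 pools collected 2 days after a fracture and 3 pools collected 6 days after a fracture, when the labels call the tissue periosteum and soft callus. The labels give day 2 for the unfractured pools, and no unfractured pool was collected at day 6. Day 6 against unfractured therefore also differs in the day of collection. The animals had 2 doses of tamoxifen of 75 µg per g and were 2 to 5.5 months old. Each pool held the cells of 4 to 9 animals, and each group had 2 male pools and 1 female pool. Of the 25697 probes, between 10387 (40.4%) and 14173 (55.2%) were detected per array, and the 75th percentile of the raw intensity ranged from 302 to 892. The p-value of a single gene rests on the spread between pools, and 3 arrays per group limit the precision of every value. The camera p-value of a list with the preset correlation compares genes with genes. It does not measure agreement between pools.

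Macrophage and pan-leukocyte transcripts were high in 1 pool of each group, in each case a male pool. The mean log2 intensity of 35 macrophage and pan-leukocyte genes was 10.32 in unfractured replicate 3, 11.94 in day 2 replicate 1 and 10.23 in day 6 replicate 1, and lay between 6.98 and 8.22 in the other 6 pools. Lyz2, the lysozyme of macrophages and neutrophils, had log2 intensities of 15.19, 15.75 and 14.57 in those 3 pools, and of 10.13 to 11.94 in the others. C1qb, a complement subunit made by macrophages, had 12.67, 13.96 and 12.09 in them and at most 9.25 elsewhere; both genes were chosen for this after their values were seen. Neither the macrophage list (smallest adjusted p = 0.0996) nor the pan-leukocyte list (smallest adjusted p = 0.124) passed the test between any pair of groups, though with the replicate number as a block the pan-leukocyte list was lower at day 6 than at day 2 (adjusted p = 0.0407; adjusted p = 0.806 with an estimated correlation). These 3 arrays are called leukocyte-rich by that mean alone. Neutrophil transcripts were as high in another pool: the mean of 14 neutrophil genes was 12.00 in unfractured replicate 1, against 11.84, 13.75 and 11.65 in the 3 leukocyte-rich arrays and 9.21 to 10.11 in the other 5. The 3 leukocyte-rich arrays are 1 per group, so values are also given for the other 6 arrays and, without a test, for the 3 leukocyte-rich arrays alone; this division was chosen after the values were seen. Signal moves with group in the 6 arrays: the 2 unfractured pools detected 40.4% and 46.4% of probes, with 75th percentiles of 302 and 350, and the 4 fracture pools 52.1% to 55.2%, with 647 to 892. The mean of the macrophage list, given without a test, differs by group there too. It was 7.53 and 7.07 in the unfractured pools, 8.13 and 8.79 at day 2 and 7.98 and 8.38 at day 6. Most genes of the list did not pass at day 2 in the 6 arrays. The 6 arrays hold 1 male and 1 female pool per group.

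**Figure D1:**
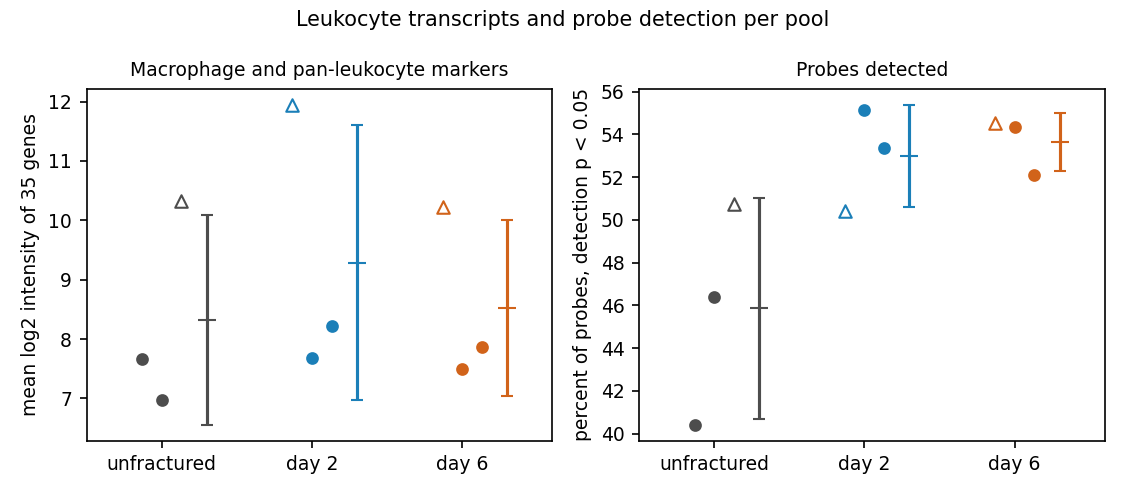
The panel of leukocyte markers plots the mean log2 intensity of 35 macrophage and pan-leukocyte genes per pool and the panel of detection plots the percent of probes detected; each point is a pool, open triangles are the leukocyte-rich pools, and bars give the mean and SD of 3 pools. The triangles lie at 10.23 to 11.94 and the other pools at 6.98 to 8.22, while detection ranges from 40.4% to 55.2%.

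The comparison of day 6 with unfractured periosteum asks how the labelled cells of the early callus differ from those of intact periosteum. Cartilage genes rose most. Acan, which encodes the large proteoglycan of cartilage, was at least 449-fold higher at day 6 (limma adjusted p = 4.21e-05, n = 3 pools per group). Col9a2, a collagen of cartilage fibrils, was at least 233-fold higher, and Hapln1, which links aggrecan to hyaluronan, at least 129-fold. Col10a1, the collagen of hypertrophic cartilage, was at least 44.2-fold higher and the cartilage genes Ucma, Matn1 and Mia at least 48.9-fold, 40.5-fold and 37.9-fold. No probe of these genes was detected in any unfractured pool. Among genes detected in both groups, Scrg1 rose by 6.64 ± 0.43 on the log2 scale (SE, n = 3 pools per group), Col2a1, the main collagen of cartilage, by 6.42 ± 1.19 and Panx3 by 6.35 ± 0.89. Sox9, the transcription factor that chondrocyte formation needs, rose by 3.54 ± 0.61. Of the 19 measured genes of the cartilage list 12 rose and 0 fell (15 rose adjusted over the list alone), with a median log2 change of 3.73, or 3.54 with the 7 undetected members at their bound. The list passed the camera test (adjusted p = 1.04e-15), which it did not with an estimated correlation (adjusted p = 0.119). Its median was 3.96 in the 6 arrays with the lower marker mean and 3.72 in the 3 leukocyte-rich arrays. Acan, Col9a2, Hapln1, Ucma, Scrg1, Mia and Matn1 passed in all 26 alternative settings. The calls of Col10a1, Panx3 and Sox9 ended without day 6 replicate 2 or day 6 replicate 3 (highest adjusted p over all settings 0.0754, 0.0629 and 0.108), and that of Col10a1 also without unfractured replicate 2. The call of Col2a1 ended without any 1 of the 3 day 6 pools and without unfractured replicate 1 or 2, and with the replicate block (highest adjusted p over all settings 0.122).

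**Figure D2:**
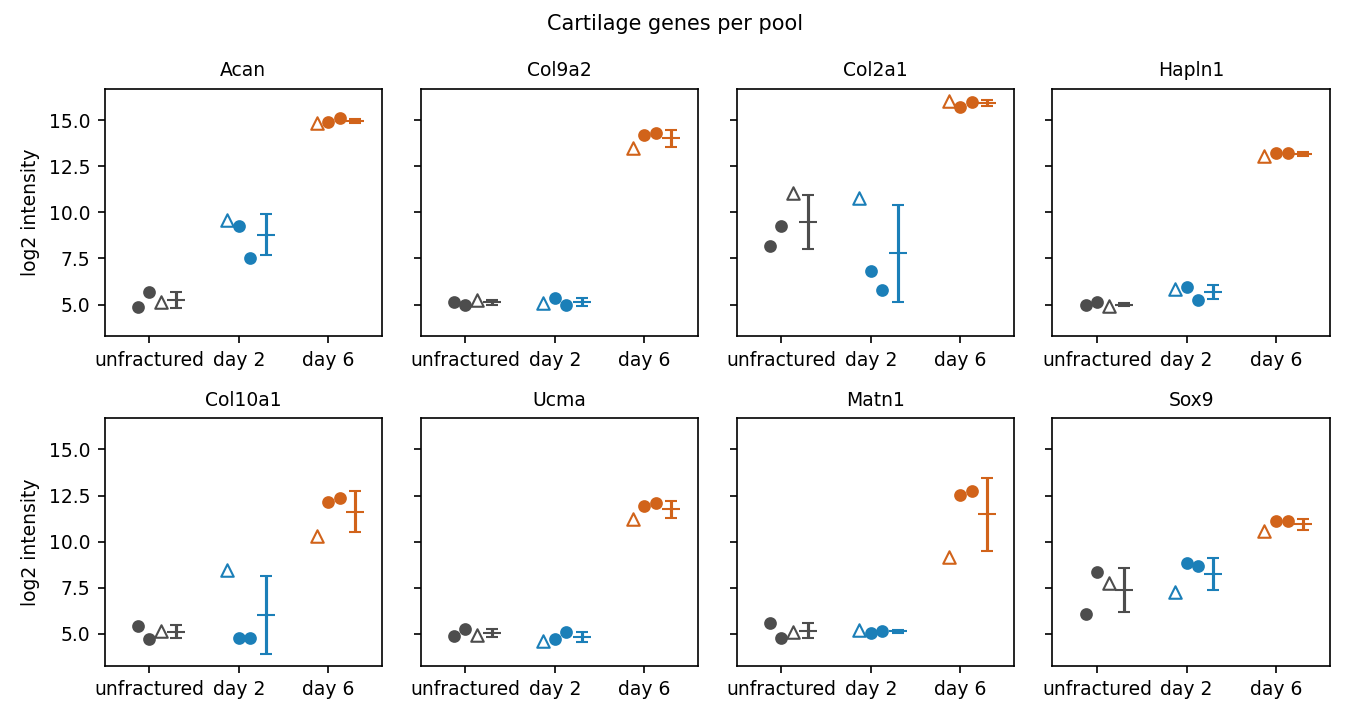
Each panel plots the log2 intensity of a cartilage gene per pool at the 3 times; points are pools, open triangles are the leukocyte-rich pools, and bars give the mean and SD of 3 pools. For Acan, Col9a2, Hapln1, Ucma and Matn1 every day 6 pool lies above every other pool.

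The lists of collagen and matrix, hypoxia and glycolysis, and osteoblast genes were higher as well, with the preset correlation between genes and not with an estimated one, and few of their genes passed singly. In the list of collagens and fibrillar matrix 7 of 38 measured genes rose and 0 fell (15 rose adjusted over the list alone). P4ha3 and Plod2, which hydroxylate collagen, rose by 2.91 ± 0.52 and 2.70 ± 0.46. Loxl2, which crosslinks it, rose by 1.83 ± 0.34, and Fbn2 was at least 1.67-fold higher. The bulk collagens Col1a1 (log2 change 0.81 ± 0.32, adjusted p = 0.199) and Col3a1 (0.85 ± 0.52, adjusted p = 0.391) did not pass. The list's median was 0.96 (camera adjusted p = 8.92e-07; adjusted p = 0.596 with an estimated correlation), 1.40 in the 6 arrays and 0.62 in the leukocyte-rich arrays. Of the hypoxia and glycolysis list 4 of 23 genes rose and 0 fell (8 rose adjusted over the list alone). The carbonic anhydrases Car12 and Car9 rose by 4.71 ± 0.51 and 3.93 ± 0.29. Of the glycolytic enzymes, Pgam1 rose by 1.56 ± 0.28 and Aldoc was at least 11.2-fold higher. Its median was 0.42 (adjusted p = 1.17e-04; adjusted p = 0.593 with an estimated correlation), 0.37 in the 6 arrays and 1.14 in the leukocyte-rich arrays. Of 18 osteoblast genes 1 rose (3 adjusted over the list alone), Postn, an extracellular matrix protein of periosteum, at least 2.56-fold. Sp7, a transcription factor of osteoblasts, had a log2 change of 1.95 ± 0.74 (adjusted p = 0.186). Runx2 and Spp1 were not measured. The osteoblast list's median was 0.80 (adjusted p = 0.00301; adjusted p = 0.596 with an estimated correlation), 0.95 in the 6 arrays and 0.95 in the leukocyte-rich arrays. With the preset correlation the osteoblast list did not pass without day 6 replicate 1, the leukocyte-rich pool of that group, though it passed in the 6 arrays. The calls of P4ha3, Plod2, Loxl2 and Pgam1 ended without unfractured replicate 1 or 2 or day 6 replicate 3 and in a fit of only these groups (highest adjusted p over all settings 0.107, 0.0951, 0.140 and 0.0961). Apart from that of Plod2 they also ended without day 6 replicate 2, that of P4ha3 also without day 6 replicate 1 and that of Loxl2 also without day 2 replicate 3. Those of Postn and Fbn2 ended without day 6 replicate 2 or 3 (highest adjusted p 0.0738 and 0.0690), that of Fbn2 also under median scaling, and that of Car9 when all probes were read (adjusted p = 0.100).

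Of the Wnt, BMP and TGF-beta, and growth factor lists only the Wnt list passed, with the preset correlation. Few of their genes passed singly. Of 26 genes of the Wnt list 2 rose (4 adjusted over the list alone). Frzb, a secreted antagonist of Wnt ligands, was at least 14.6-fold higher, and Rspo3, a secreted enhancer of Wnt signalling, rose by 2.18 ± 0.33. The list's median was 0.36 (adjusted p = 0.0331; adjusted p = 0.596 with an estimated correlation), and 0.32 in the leukocyte-rich arrays. It was 0.63 in the 6 arrays, where the list did not pass (adjusted p = 0.0788). In the BMP and TGF-beta list, which did not pass (adjusted p = 0.791), 3 genes rose and 1 fell. Gdf5, a growth factor of joint and cartilage formation, was at least 3.16-fold higher. Inhba rose by 1.48 ± 0.32 and Tgfbi by 1.30 ± 0.25, and Bmp4 fell by 2.24 (± 0.42). The list of growth factors and receptors did not pass (adjusted p = 0.842). In it Fgfr3, a receptor of growth plate chondrocytes, rose by 2.35 ± 0.31, Mdk rose by 2.17 ± 0.38 and Vegfc, a lymphatic growth factor, fell by 1.94 (± 0.33). Inhba, Tgfbi and Bmp4 passed in 14, 14 and 16 of 26 alternative settings (highest adjusted p 0.207, 0.167 and 0.138). Their calls and that of Vegfc (highest adjusted p 0.213) ended without unfractured replicate 1 or 2 or day 6 replicate 2 or 3. The first 3 also ended without day 2 replicate 3, those of Tgfbi and Bmp4 without day 2 replicate 2, those of Inhba and Tgfbi without day 6 replicate 1, and those of Bmp4 and Vegfc under median scaling. The calls of Rspo3 and Mdk ended without day 6 replicate 2 or 3, and that of Mdk also without unfractured replicate 2 and with all probes (highest adjusted p 0.0896 and 0.122). A fit of only these groups ended the calls of Inhba, Tgfbi, Bmp4, Rspo3 and Mdk, sex in the model those of Inhba, Tgfbi and Bmp4, all probes those of Inhba and Tgfbi, the replicate block that of Tgfbi, and no detection filter and weights by the animals pooled that of Inhba. Of 8 measured Schwann cell genes 1 rose, S100b, at least 1.33-fold, which chondrocytes also express; it passed in 16 of 26 alternative settings and was lost without unfractured replicate 1 or 2 or any 1 of the day 6 pools, with the deposited value table, under median scaling, without background correction and in a fit of only these groups (highest adjusted p 0.127). That list's median was 1.12, or 0.64 with undetected members at their bound (adjusted p = 0.0399; adjusted p = 0.596 with an estimated correlation). It was 0.89 in the 6 arrays, where it did not pass (adjusted p = 0.249), and 1.14 in the leukocyte-rich arrays.

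Vascular and contractile lists were lower at day 6, though few of their genes passed singly. Of 19 endothelial genes 1 fell (7 adjusted over the list alone), Vwf, the clotting factor of endothelial cells, by 3.44 (± 0.57). The endothelial median was -1.77 (camera adjusted p = 8.92e-07; adjusted p = 0.596 with an estimated correlation). It was -2.77 in the 6 arrays, where 16 of the 19 genes fell, and 0.15 in the 3 leukocyte-rich arrays, so the relation did not hold there. Of 21 pericyte and smooth muscle genes 0 fell and 1 rose, the proteoglycan Cspg4 (1.98 ± 0.35), whose call ended without unfractured replicate 2 or day 6 replicate 2 or 3 and in a fit of only these groups (highest adjusted p over all settings 0.129). Their median was -1.44 (adjusted p = 4.78e-05; adjusted p = 0.614 with an estimated correlation). It was -2.25 in the 6 arrays, where 16 fell and 1 rose, and -0.26 in the leukocyte-rich arrays. Acta2, the gene whose promoter drives the label, had a log2 change of -1.05 ± 0.52 (adjusted p = 0.290). Of 27 Notch pathway genes 0 passed, and their median was -0.92 (adjusted p = 0.00301; adjusted p = 0.593 with an estimated correlation). Without the leukocyte-rich arrays 14 Notch genes fell and 2 rose, with a median of -0.91, and in the leukocyte-rich arrays the median was 0.04. The receptors Notch1, Notch2 and Notch3 had log2 changes of -1.39 ± 0.48, -1.47 ± 0.54 and -1.98 ± 0.88 over all arrays, and the target gene Hes1 had -1.77 ± 0.50 (adjusted p = 0.101). Notch signalling was the subject of the study known for these samples, so this list is not independent evidence of its direction.

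Other lists were lower at day 6 as well. Of 16 adipocyte genes 2 fell (6 adjusted over the list alone). Pparg, the master transcription factor of fat cells, fell by 1.66 (± 0.28) and the lipase Pnpla2 fell by 2.43 (± 0.50). The call of Pparg ended without unfractured replicate 1 or 2 or day 6 replicate 2 or 3 and under median scaling (highest adjusted p 0.247). Medians were -0.66 for the adipocyte list (adjusted p = 0.00427; adjusted p = 0.510 with an estimated correlation), -1.28 for skeletal muscle (adjusted p = 0.00119; adjusted p = 0.758 with an estimated correlation) and -1.34 for neutrophil genes (adjusted p = 0.0399; adjusted p = 0.870 with an estimated correlation). No muscle or neutrophil gene passed singly. These medians were -0.74, -1.59 and -1.87 in the 6 arrays and -0.09, -0.42 and -0.35 in the leukocyte-rich arrays. The neutrophil list passed in 16 of 25 alternative settings and the Schwann cell list in 13, and the muscle list did not pass without unfractured replicate 2. The lists of mesenchymal progenitor, interferon response and immediate early genes had medians of -0.50, -0.72 and -0.67, which under median scaling lay above 0 and below that of all genes. Their adjusted p were 0.0155, 4.55e-04 and 1.17e-04, and adjusted p = 0.596 with an estimated correlation for all 3. Their medians were -0.63, -0.96 and -0.89 in the 6 arrays and -0.16, -0.58 and -0.26 in the leukocyte-rich arrays. The progenitor list did not pass under median scaling or without unfractured replicate 2. Of the interferon genes 1 fell, Ifi47, which fell by 2.01 (± 0.41). Pnpla2 and Ifi47 passed in 12 and 13 of 26 alternative settings (highest adjusted p 0.180 and 0.190) and were lost under median scaling and without unfractured replicate 1 or 2, day 2 replicate 2 or 3, or any 1 of the day 6 pools. Both also ended in a fit of only these groups, with sex in the model, with the replicate block and with weights by the animals pooled, and Pnpla2 without a detection filter. Under median scaling the median of all genes was 0.83 for day 2 against unfractured, 0.72 for day 6 against unfractured and -0.13 for day 6 against day 2, where it had been 0.06, 0.04 and -0.04, so changes under it are read relative to that median. Beside Vwf, the largest falls among single genes were those of Gsn, an actin-severing protein, which fell by 4.44 (± 0.81), and of Timp4, an inhibitor of metalloproteases, which fell by 3.42 (± 0.61). Inmt fell by 3.36 (± 0.54), Hoxb4 fell by 3.02 (± 0.58) and Sult1a1 fell by 2.95 (± 0.48). Fam107a was at least 9.73-fold lower. The calls of Gsn, Vwf, Timp4, Hoxb4 and Sult1a1 ended when unfractured replicate 1 or 2, or day 6 replicate 2 or 3, was left out, and those of Gsn and Inmt also under median scaling. That of Inmt ended as well without unfractured replicate 1 or 2 or day 6 replicate 3, and that of Fam107a without unfractured replicate 2 or day 6 replicate 2 or 3 (highest adjusted p 0.0742 and 0.0935). Those of Gsn and Hoxb4 also ended without day 2 replicate 2, that of Hoxb4 without day 2 replicate 3, and those of Vwf, Timp4 and Hoxb4 in a fit of only these groups. That of Timp4 ended further without day 6 replicate 1, with the deposited value table, without background correction and with weights by the animals pooled. Over all settings the highest adjusted p of Gsn, Vwf, Timp4, Hoxb4 and Sult1a1 were 0.0951, 0.0984, 0.114, 0.147 and 0.0962.

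Between day 6 and unfractured periosteum, limma passed 284 of 10073 genes, 221 higher and 63 lower at day 6, and for 25.9% of all genes the pools of the groups did not overlap, where chance gives 10%. Median scaling gave 264 higher and 7 lower, and a fit of only these groups gave 139. The count was 123 without unfractured replicate 1, 108 without replicate 2 and 1568 without replicate 3. It was 53 and 54 without day 6 replicates 2 and 3, and 181 and 174 without day 2 replicates 2 and 3, which share in the estimate of the spread. In the 6 arrays with the lower marker mean 3068 genes passed, among them all 284, and with the leukocyte-rich arrays as a block 941 did. Of the 3068 genes, 62.5% changed in the same direction between the leukocyte-rich arrays. Over all genes the log2 changes of these 2 sets of arrays correlated at 0.31. Of the 46 named genes that passed, 12 passed in all 26 alternative settings, 13 were lost under median scaling, 30 at an adjusted p under 0.01, and 30 and 32 were lost without day 6 replicate 2 and without day 6 replicate 3. Of the 34 lists tested 6 were higher and 9 lower, and 0 of these passed with an estimated correlation.

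The comparison of day 6 with day 2 asks what changed between the early response and the soft callus. Cartilage genes rose here too. Col9a2 was at least 335-fold higher at day 6, Ucma at least 70.3-fold, Matn1 at least 58.3-fold and Mia at least 54.6-fold. Col2a1 rose by 8.13 ± 1.19 on the log2 scale (SE, n = 3 pools per group), Hapln1 by 7.47 ± 0.25, Scrg1 by 6.19 ± 0.43 and Acan by 6.16 ± 0.51. Of the 19 cartilage genes 13 rose and 0 fell (18 rose adjusted over the list alone), with a median of 3.96. This list alone passed the camera test both ways (adjusted p = 2.53e-30; adjusted p = 0.0219 with an estimated correlation); its median was 4.21 in the 6 arrays and 3.44 in the leukocyte-rich arrays. With the replicate number as a block it passed with the preset correlation (adjusted p = 5.12e-25) and no longer with an estimated one (adjusted p = 0.157). Col9a2, Hapln1, Ucma, Matn1, Scrg1, Acan and Mia passed in all 26 alternative settings, while the call of Col2a1 ended without day 2 replicate 2 or 3 or day 6 replicate 2 or 3, and with the replicate block (adjusted p = 0.0518; highest over all settings 0.0724).

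The lists of growth factor, matrix, osteoblast, hypoxia and Wnt genes were higher than at day 2, with the preset correlation between genes and not with an estimated one. In the list of growth factors and receptors 3 of 31 genes rose and 0 fell (4 rose adjusted over the list alone). Mdk rose by 3.69 ± 0.38, Igf2, an insulin-like growth factor, by 2.52 ± 0.46, and Fgfr3 was at least 7.99-fold higher. The median was 0.43 (adjusted p = 2.92e-04; adjusted p = 0.335 with an estimated correlation). Of 38 collagen and matrix genes 2 rose (13 adjusted over the list alone), P3h2, a collagen prolyl hydroxylase, by 2.62 ± 0.40 and Fbn2 by 1.49 ± 0.25. The median was 0.79 (adjusted p = 6.62e-11; adjusted p = 0.335 with an estimated correlation). Of 18 osteoblast genes 1 rose (4 adjusted over the list alone), Postn, at least 3.69-fold, with a list median of 1.31 (adjusted p = 6.15e-07; adjusted p = 0.335 with an estimated correlation). Of 23 hypoxia and glycolysis genes 3 rose (6 adjusted over the list alone). Aldoc was at least 16.2-fold higher, Car9 rose by 3.46 ± 0.29 and Car12 by 3.08 ± 0.51. The median was 0.45 (adjusted p = 2.46e-05; adjusted p = 0.335 with an estimated correlation). The Wnt list had a median of 0.59 (adjusted p = 7.88e-05; adjusted p = 0.335 with an estimated correlation), and its 1 gene that rose was the antagonist Frzb, at least 21.1-fold. The medians of these lists were 0.52, 0.71, 1.497, 0.19 and 0.36 in the 6 arrays, and in the leukocyte-rich arrays 1.02, 1.13, 1.16, 0.93 and 0.96. Comp, a cartilage and tendon matrix protein, rose by 3.96 ± 0.62 and was the 1 gene of the tendon list to pass (median 1.26, adjusted p = 0.00253; adjusted p = 0.545 with an estimated correlation). Gdf5, at least 4.55-fold higher, was the 1 gene of the BMP and TGF-beta list to pass (median 0.16, adjusted p = 0.0419; adjusted p = 0.597 with an estimated correlation), and that list did not pass in the 6 arrays (adjusted p = 0.252). The Schwann cell list was higher with 0 genes passing singly (median 0.78, adjusted p = 0.00242; adjusted p = 0.335 with an estimated correlation). So was the list of lineage transcription factors (median 0.33, adjusted p = 0.0344; adjusted p = 0.693 with an estimated correlation), which did not pass in the 6 arrays (adjusted p = 0.144). For the tendon, BMP, Schwann cell and lineage lists the medians were 1.34, 0.18, 0.47 and 0.23 in the 6 arrays and 0.72, 0.50, 1.04 and 0.47 in the leukocyte-rich arrays. The BMP list and the lineage list each passed in 14 of 25 alternative settings. The calls of Igf2, P3h2, Fbn2, Postn, Car12 and Comp ended without day 2 replicate 3 or day 6 replicate 2 or 3 (highest adjusted p over all settings 0.188, 0.0956, 0.157, 0.0907, 0.103 and 0.109), and all but that of Postn without day 2 replicate 1. Those of Igf2, Postn and Car12 also ended without day 2 replicate 2, those of P3h2, Fbn2 and Car12 without day 6 replicate 1, and that of Igf2 without unfractured replicate 2. Median scaling ended those of Igf2 and Fbn2, and that of Car12 ended in the 6 arrays. The calls of Postn and Fbn2 also ended with the deposited value table and without background correction, those of Igf2 and Car12 with weights by the animals pooled, and that of Igf2 with sex in the model and without a detection filter. With the replicate block the calls of Igf2, Car12 and Comp ended (adjusted p = 0.0820, 0.0718 and 0.0612), and when all probes were read that of Car9 did (adjusted p = 0.0989).

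Proliferation genes were lower at day 6 than at day 2. All 33 measured cell cycle genes had a negative log2 change, with a median of -1.04, and 1 fell singly (6 adjusted over the list alone): Mcm4, a subunit of the replicative helicase, by 1.35 (± 0.24). The list's adjusted p was 1.02e-10, and adjusted p = 0.545 with an estimated correlation; its median was -1.01 in the 6 arrays and -1.22 in the leukocyte-rich arrays. All 19 ribosome biogenesis genes were negative as well, with a median of -0.61 (0 fell over all genes and 5 adjusted over the list alone; adjusted p = 1.06e-06; adjusted p = 0.335 with an estimated correlation), -0.76 in the 6 arrays and -0.48 in the leukocyte-rich arrays. Skeletal muscle genes had a median of -1.46 (adjusted p = 2.46e-05; adjusted p = 0.623 with an estimated correlation) and oxidative phosphorylation genes of -0.31 (adjusted p = 0.00362; adjusted p = 0.545 with an estimated correlation), and 0 genes of either list passed singly. Their medians were -1.49 and -0.32 in the 6 arrays and -1.46 and -0.18 in the leukocyte-rich arrays, and the oxidative phosphorylation list did not pass under median scaling. Among single genes Ccnd1, a cyclin that drives entry into the cell cycle, fell by 1.56 (± 0.27). Rpa1, which binds single-stranded DNA during replication, fell by 1.23 (± 0.20). The neuropeptide Npy was at least 4.76-fold lower, and the carbonic anhydrase Car4 at least 6.68-fold lower. Of these falls that of Npy passed in all 26 alternative settings; those of Mcm4, Ccnd1 and Rpa1 ended under median scaling and without day 2 replicate 2 or 3 or any 1 of the day 6 pools (highest adjusted p over all settings 0.553, 0.398 and 0.572), and those of Mcm4 and Rpa1 also without day 2 replicate 1 and that of Mcm4 without unfractured replicate 2. All 3 ended with sex in the model, and those of Mcm4 and Ccnd1 with weights by the animals pooled. With the replicate block Mcm4, Ccnd1, Rpa1 and Car4 did not pass (adjusted p = 0.0665, 0.0662, 0.0662 and 0.0694). Car4 passed in 10 of 26 alternative settings (highest adjusted p 0.163); it did not pass in the 6 arrays (adjusted p = 0.0756) and was lost without any 1 of the 9 arrays other than unfractured replicate 2.

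Between day 6 and day 2, limma passed 143 genes, 132 higher and 11 lower at day 6, and 25.05% of all genes had groups that did not overlap, against 10% by chance. Median scaling gave 80, the replicate block 89 and a fit of only these groups 216. Without day 2 replicates 1, 2 and 3 the count was 95, 77 and 52, and without day 6 replicates 2 and 3 it was 47 and 49. In the 6 arrays with the lower marker mean 351 genes passed, among them 120 of the 143. Of the 351 genes, 82.6% changed in the same direction between the leukocyte-rich arrays. Over all genes the log2 changes of these 2 sets of arrays correlated at 0.50. Of the 34 lists 10 were higher and 4 lower, and 1 of these passed with an estimated correlation. The replicate block ended 15 of the 34 calls of named genes, with the same log2 changes. It kept the 14 lists with the preset correlation and added the neutrophil, pan-leukocyte and inflammatory lists as lower at day 6 (adjusted p = 0.00178, 0.0407 and 0.0407); no list passed in it with an estimated correlation.

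The comparison of day 2 with unfractured periosteum asks how the labelled cells respond first. Proliferation genes were higher at day 2: all 33 cell cycle genes had a positive log2 change, with a median of 1.33, and 0 passed over all genes (3 rose adjusted over the list alone). In the 6 arrays with the lower marker mean 13 of the 33 rose and the median was 1.87. Bub1b, a spindle checkpoint kinase, rose by 2.65 ± 0.55 there (SE, n = 2 pools per group), and the mitotic phosphatase Cdc25c, undetected in both unfractured pools, was at least 3.00-fold higher. The median in the leukocyte-rich arrays was 0.30. The cell cycle list had an adjusted p of 6.27e-10, and adjusted p = 0.721 with an estimated correlation. Ribosome biogenesis genes had a median of 0.53 (16 of 19 positive; 4 rose adjusted over the list alone; adjusted p = 9.18e-04; adjusted p = 0.721 with an estimated correlation), 0.63 in the 6 arrays and 0.17 in the leukocyte-rich arrays. Unfractured replicate 1 had the lowest cell cycle mean of all arrays, 7.24, against 9.93 in unfractured replicate 3.

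Endothelial genes had a median of -1.40 at day 2 (0 fell over all genes and 2 adjusted over the list alone; adjusted p = 5.07e-08; adjusted p = 0.721 with an estimated correlation). In the 6 arrays 16 of the 19 endothelial genes fell, with a median of -2.23. Vwf fell by 3.58 (± 0.51) there, Pecam1, an adhesion molecule of endothelial cells, fell by 3.23 (± 0.46), and Plvap fell by 3.13 (± 0.34). The median in the leukocyte-rich arrays was -0.20. Pericyte and smooth muscle genes had a median of -1.18 (adjusted p = 2.31e-05; adjusted p = 0.721 with an estimated correlation), -1.10 in the 6 arrays, where 8 of 21 fell, and -1.37 in the leukocyte-rich arrays. Notch pathway genes had a median of -0.97 (adjusted p = 0.00941; adjusted p = 0.721 with an estimated correlation). It was -1.13 in the 6 arrays, where 13 of 27 fell and 1 rose, and -0.33 in the leukocyte-rich arrays. This list is not independent evidence of its direction. Notch2 fell by 2.15 (± 0.33) in the 6 arrays, Notch1 fell by 1.79 (± 0.33) and Hey1, a Notch target, fell by 1.52 (± 0.30). Heyl, another target, had a log2 change of 0.02 ± 0.26 (limma adjusted p = 0.953). Notch2 was detected on 1 of the 2 day 2 pools of these 6 arrays. In the leukocyte-rich arrays it went the other way, with log2 intensities of 5.65 in the unfractured pool and 6.14 at day 2. Notch1 was lower at day 2 there as well (9.44 and 8.89), and so was Hey1 (10.81 and 9.13).

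The lists of growth factors (-0.52), mesenchymal progenitor (-0.48), adipocyte (-0.69), interferon response (-0.73), complement (-0.65), immediate early (-0.63) and circadian genes (-0.71) had negative medians at day 2 that lay above 0, and below that of all genes, under median scaling. Their adjusted p were 1.81e-04, 0.0232, 0.0122, 9.25e-06, 0.0284, 9.25e-06 and 0.0337, and adjusted p = 0.721 with an estimated correlation for each. Their medians were -0.39, -0.53, -0.73, -1.24, -0.44, -0.93 and -0.90 in the 6 arrays, and in the leukocyte-rich arrays -0.95, -0.61, -0.37, 0.03, -1.44, -0.27 and -0.19. The progenitor, complement and circadian lists passed in 18, 20 and 17 of 25 alternative settings, and each was lost without unfractured replicate 1 or 2 or day 2 replicate 1. Some single genes fell in the 6 arrays. Ifi47, an interferon-induced GTPase, fell by 2.54 (± 0.23), and the interferon-induced chemokine Cxcl10 fell by 1.79 (± 0.17). Clu, a secreted chaperone, fell by 3.49 (± 0.35), and Bmp4 fell by 2.39 (± 0.18). Acan, undetected in every unfractured pool, was at least 6.29-fold higher at day 2 in all 9 arrays without passing (adjusted p = 0.139), and passed in the 6 arrays, at least 4.14-fold higher (adjusted p = 0.0315). It was the 1 cartilage gene that rose there, where 7 of the 19 fell, Col2a1 by 2.42 (± 0.48). The cartilage list had a median of -0.02 (adjusted p = 0.579), and of -0.11 in the 6 arrays, where it did not pass (adjusted p = 0.104).

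With all 9 arrays limma passed 0 of 10073 genes between day 2 and unfractured periosteum (smallest adjusted p = 0.139), while 1625 had an unadjusted p under 0.05, where chance gives 504. For 18.6% of genes the groups did not overlap, against 10% by chance. Without the 3 leukocyte-rich arrays 2095 genes passed, 1089 higher and 1006 lower; with those arrays as a block 65 did, and with the leukocyte marker mean as a covariate 0 did, all 3 chosen after the values were seen. The fit of 6 arrays has 2 pools per group and 3 residual degrees of freedom, and its 2 unfractured pools had weaker signal than its 4 fracture pools. Of its 2095 genes, 57.7% changed in the same direction between the leukocyte-rich arrays of the 2 groups. Over all genes the log2 changes in the 6 arrays and in the leukocyte-rich arrays correlated at 0.15. Most of these calls thus have little backing in the arrays left out. Leaving out unfractured replicate 3 alone gave 924 genes, leaving out day 2 replicate 3 gave 1, and leaving out any other array gave 0. Of the 34 lists 2 were higher and 10 lower, and 0 of these passed with an estimated correlation.

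**Figure D3:**
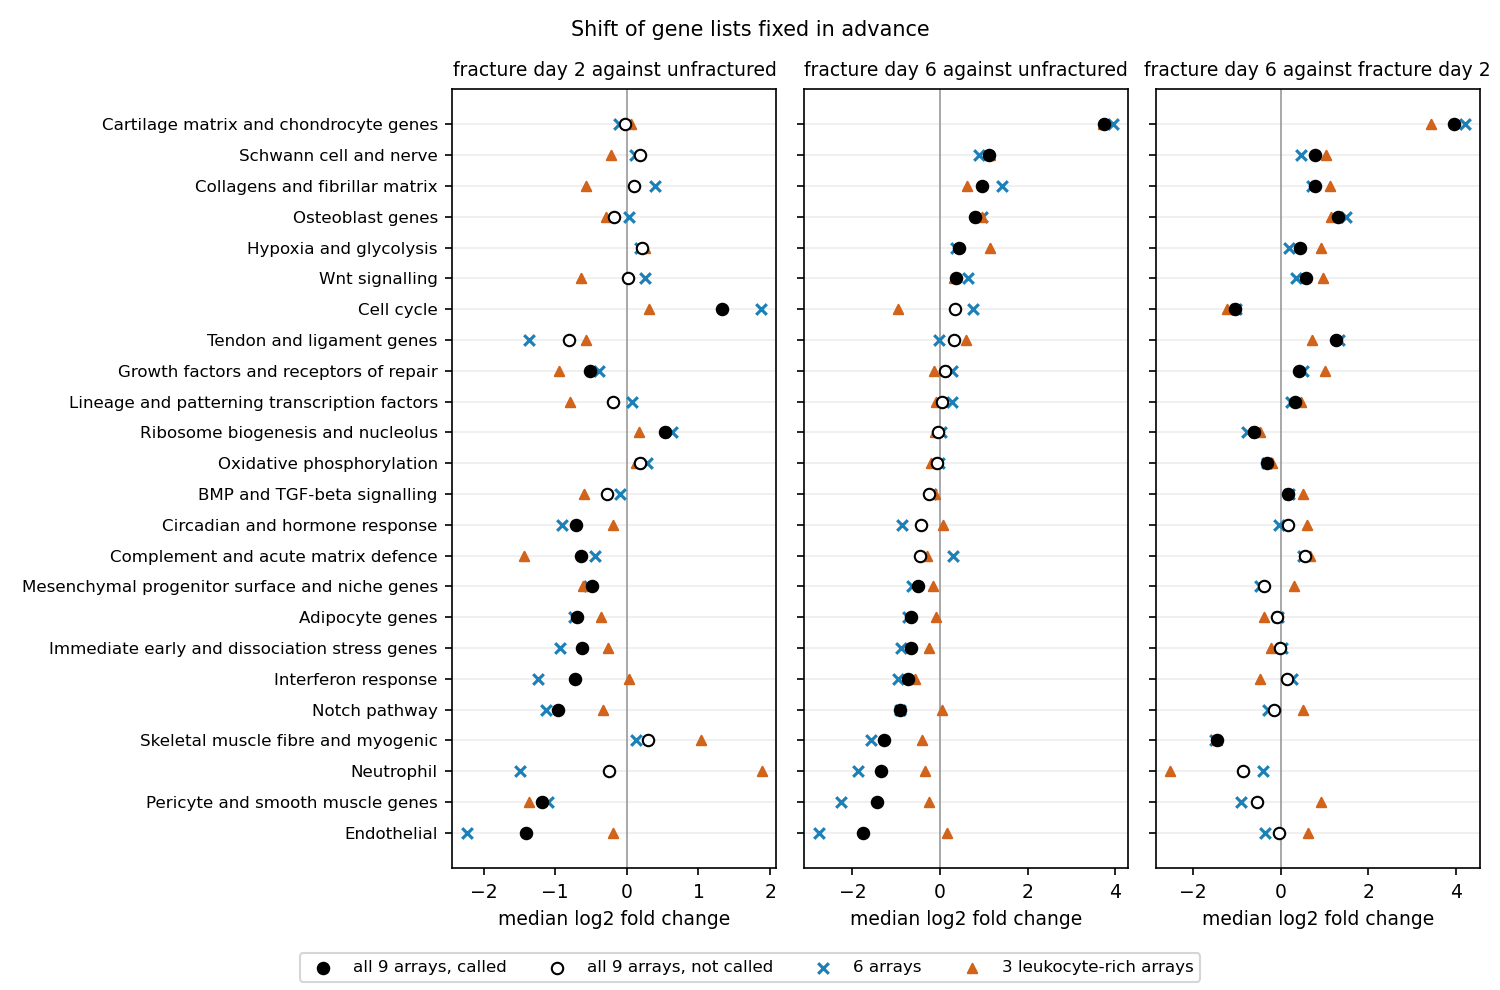
For each list called in at least 1 comparison, the axis gives the median log2 fold change of its measured members; filled circles are lists that passed with all 9 arrays, open circles those that did not, crosses the 6 arrays with the lower marker mean and triangles the 3 leukocyte-rich arrays. The cartilage list lies at 3.73 and 3.96 in the comparisons with day 6, and under median scaling the negative medians of growth factor, progenitor, adipocyte, interferon, complement, immediate early and circadian genes at day 2, and of progenitor, interferon and immediate early genes at day 6, lie above 0.

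**Figure D4:**
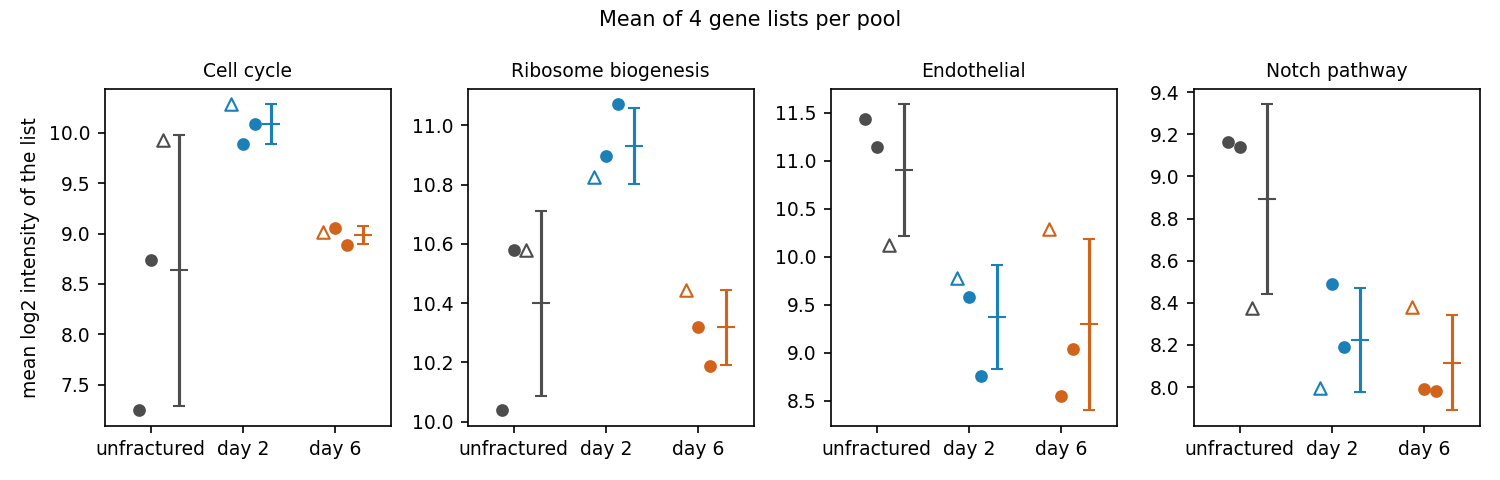
Each panel plots the mean log2 intensity of the measured members of a list per pool; points are pools, open triangles are the leukocyte-rich pools, and bars give the mean and SD of 3 pools. The cell cycle mean spans 7.24 to 9.93 in the unfractured pools.

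Sex was compared because each group held 1 female pool. With group in the model 2 genes differed between female and male pools: Eif2s3y, on the Y chromosome, was lower in female pools by a log2 difference of -5.49 ± 0.21 (limma adjusted p = 6.09e-05) and Xist, which silences an X chromosome, was higher by 4.72 ± 0.24 (adjusted p = 2.29e-04). Both separated all 9 pools as the labels give their sex. For the fracture response by sex limma passed 0 genes, with 28 at an unadjusted p under 0.05, where chance gives 504. With 1 female pool per group that fit has 3 residual degrees of freedom, all from the 2 male pools of each group. In every group 1 of these male pools is leukocyte-rich and the other is not, so the spread of that fit holds this difference. The test therefore cannot show whether the response differs by sex. The 3 leukocyte-rich pools are all male, so leukocyte content is partly tied to sex.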

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

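The tests on leukocyte RNA, weak hybridisation, dilution and endothelial cells were chosen after the values they measure, or some of them, had been seen; the others were chosen before.

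The change from unfractured differed between day 6 and day 2 in opposite directions for some lists, which the comparison of day 6 with day 2 tests directly. The cell cycle effect was lower at day 6 by a median log2 difference of -1.04 and the ribosome biogenesis effect by -0.61, and the growth factor effect was higher by 0.43; each passed the camera test with the preset correlation and none with an estimated one (adjusted p = 0.545, 0.335 and 0.335). Probes without a gene symbol, which the comparisons of genes leave out, also changed: of 858 tested, 14 passed at day 6 against unfractured (13 higher, 1 lower) and 11 at day 6 against day 2 (10 higher, 1 lower).

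Macrophage and pan-leukocyte transcripts were higher in 3 arrays, 1 per group. Weak hybridisation would make those arrays detect the fewest probes of their groups, and only 1 of the 3 did. By the raw 75th percentile, however, day 2 replicate 1 (351 against 892 and 759) and day 6 replicate 1 (333 against 679 and 647) had the weakest signal of their groups. Unfractured replicate 3 had the strongest of its group (434 against 302 and 350). Weak signal is thus not shared by all 3 arrays, and it stays open for the 2 fracture arrays. RNA of mixed leukocytes, neutrophils among them, cannot be told apart from other sources: of 14 neutrophil genes, none of which chose the arrays, 100% lay above both other arrays of the group in day 2 replicate 1 and day 6 replicate 1, and 35.7% in unfractured replicate 3, where 41.1% of all genes did. S100a8, the most abundant of them, was at 15.59 to 16.09 in the 3 arrays and at 15.75 in unfractured replicate 1, although sorting for tomato would remove unlabelled leukocytes. Of the 35 markers that chose the arrays 0 are in another list and 30 were detected on at least 3 of the 6 other arrays, and with 1 such array per group no biological explanation was tested.

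No gene passed at day 2 with all 9 arrays, while 2095 did without the 3 leukocyte-rich arrays, 65 with them as a block and 0 with the marker mean as a covariate. Few of the genes gained followed the marker mean within groups, 3.58% at r over 0.9 against 4.87% of all genes. The mean of the macrophage list, however, was higher in the fracture pools than in the unfractured pools of the 6 arrays. There 6 of the 20 macrophage and 2 of the 15 pan-leukocyte genes are among those gained, all higher at day 2. Mrc1 had a log2 change of 3.53 and Adgre1 of 3.03, and C1qb was at least 5.04-fold higher. Arrays chosen by these genes give no independent test of them. Loss of weak transcripts to background in the 2 unfractured arrays of that fit, which detected 40.4% and 46.4% of probes against 52.1% to 55.2% in its fracture arrays, would leave few calls among the third of genes with the highest mean, and 21.41% of these passed against 20.80% of all genes; other effects of signal strength move with the groups there and stay open. Spread between arrays that comes with leukocyte content stays open. Among the 27 ways to leave out 1 array per group this one ranked 1 by genes passed, and the highest other gave 3. The count of 2095 itself was known before that test. Arrays that stand apart for any reason could give the same rank, so it cannot point to leukocyte content. The marker mean as a covariate, which does use that content, gave 0. The response to fracture, which the groups name, stays open and untested for the genes gained.

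The Notch, endothelial and pericyte lists were lower after fracture. Dilution of the labelled cells by leukocyte RNA in the leukocyte-rich arrays would bring the Notch median at day 2 near 0 once they are left out, and it was -1.13 without them. The mean of the macrophage list was still higher at day 2 in the 6 arrays left (8.13 and 8.79 against 7.53 and 7.07). The test therefore cannot exclude dilution there, and it covers the Notch list only. Fewer endothelial cells in the fracture sorts cannot be told apart from lower Notch expression within cells, although sorting for tomato would remove unlabelled endothelial cells: without the 3 arrays the 8 Notch genes of an endothelial subset had medians of -1.29 at day 2 and -2.27 at day 6, and the 19 others, which went both ways, had 0.02 at day 2 (quartiles -1.51 and 0.33) and -0.47 at day 6 (quartiles -1.85 and 0.36). In the 3 leukocyte-rich arrays the endothelial and Notch medians at day 6 were 0.15 and 0.04, so the fall is not seen in every set of arrays; the abundant endothelial genes Plvap and Esam had log2 intensities of 12.93 to 13.71 and 12.20 to 13.80 in the unfractured pools. The fracture itself, which the groups name, stays open beside these.

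For 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real split gave 284 genes at day 6 against unfractured and 143 at day 6 against day 2, each reached in 1 of the 10 splits with 0 as the highest other, and at day 2 it gave 0, as all 10 did. For lists the real splits gave 12, 15 and 14 and the highest others 20, 16 and 22, with 5, 5 and 7 of 10 splits giving as many; the highest in each case put leukocyte-rich arrays together, but splits that kept them apart also gave more lists than the real one, 13 at day 2 and 20 and 19 at day 6 against day 2, so this grouping does not account for all of them. With those arrays as a block 16, 14 and 19 lists passed. Of the 10 splits for day 6 against day 2, the 4 that part all 3 pairs of the same number gave 143 genes in the real split and 0 in the others, and 14 lists against at most 20; the 6 others part 1 pair. For sex, 2 of the 81 splits of 9 arrays that could be fitted gave at least the 2 genes found, a share under 0.05. Both set 1 array of each group against the rest, as the sexes do. Only a part of the 81 splits has that form, so the share cannot exclude chance. The genes found, Eif2s3y and Xist, are linked to sex. The highest other split gave 1318 and set the 3 leukocyte-rich arrays against the rest, a structure of the samples.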

How the results depend on the processing

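The settings without the 3 leukocyte-rich arrays, with those arrays as a block and with the leukocyte marker mean were chosen after seeing the data. Counts of genes for day 2 against unfractured, day 6 against unfractured and day 6 against day 2 are given in that order. Estimated array weights gave 5133, 5354 and 3435 (the weights did not converge in limma), leaving out the leukocyte-rich arrays 2095, 3068 and 351, their block 65, 941 and 307, and the marker mean 0, 939 and 258. An adjusted p under 0.01 gave 0, 64 and 53, and fitting only the groups compared 0, 139 and 216; median scaling (80) and the replicate block (89) lowered the count for day 6 against day 2. Apart from the stricter threshold, the cause was not tested. Leaving out 1 array gave 0 to 924, 53 to 1568 and 47 to 189 genes. The lists that passed numbered 0, 0 and 1 with an estimated correlation, and 19 at day 2 without the leukocyte-rich arrays; every other setting kept the counts of lists within 1.5 times. The 2 genes that differ by sex became 0 under the stricter detection filter. That filter asks for detection on all 3 pools of at least 1 group, and each group holds both sexes. It thus removes genes detected in only 1 sex before the test, so this 0 does not weigh on the 2 genes. Over 506 pairs of a named gene and a comparison and 26 settings, 11825 values stayed on their side of the threshold, 421 lost their call and 870 gained one. Pairs whose gene the stricter detection filter removed were not counted for that setting. A change of direction was counted only where the gene passed in the main fit or in the setting, and 1 such value turned. Values that passed in neither count as unchanged whatever their sign. The value that turned was Rtn4 at day 6 against day 2, at 0.352 with all probes, where another probe of the gene is read. Slide as a block was not run, since the files give no slide. Signal over background limits genes undetected in a group to a lower bound.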

Other observations

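In the 6 arrays with the lower marker mean, a fit chosen after the values were seen in which 2095 of 10073 genes passed at day 2 against unfractured periosteum, the list of inflammatory cytokines and chemokines was higher at day 2. Its median was 1.07 (camera adjusted p = 0.0385; adjusted p = 0.497 with an estimated correlation), and -0.14 in the leukocyte-rich arrays; with all 9 arrays the list did not pass (adjusted p = 0.259). Of its 34 genes 10 rose and 3 fell in the 6 arrays, and Saa3, an acute phase protein, rose by 4.25 ± 0.54 on the log2 scale (SE, n = 2 pools per group; limma adjusted p = 0.0195). Some macrophage genes were higher at day 2 in the same arrays, which were chosen by the mean of these genes among others, but most of the list did not pass. The list's median was 0.50. The log2 change was 3.53 for Mrc1 and 3.03 for Adgre1, and Ms4a7 and Cd163, undetected in both unfractured pools, were at least 3.96-fold and 2.14-fold higher. Cd74, by contrast, had a log2 change of 0.12 (limma adjusted p = 0.922). Of 23 genes of the unfolded protein response 12 rose and 3 fell in the 6 arrays, among them the chaperone Hyou1 (1.48 ± 0.38) and Creld2 (1.26 ± 0.23), while Ddit3, a stress transcription factor, fell by 1.56 (± 0.23); the list did not pass there (adjusted p = 0.0616).

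Of 38 collagen and matrix genes 9 rose and 3 fell at day 2 in those 6 arrays, among them P4ha3, undetected in both unfractured pools and at least 1.86-fold higher, and Lox, which crosslinks collagen (1.85 ± 0.21). The list's median was 0.40 (adjusted p = 0.0238; adjusted p = 0.497 with an estimated correlation), and -0.57 in the leukocyte-rich arrays. Of 18 osteoblast genes 1 rose and 3 fell, and the list did not pass (adjusted p = 0.274); Bglap2, which encodes osteocalcin, fell by 5.39 (± 0.87). Among other single genes Timp1, an inhibitor of metalloproteases, rose by 2.67 ± 0.35, and Chad, a cartilage matrix protein, fell by 4.11 (± 0.45). In the 3 leukocyte-rich arrays the log2 changes were -0.21 for Lox, -0.24 for Timp1, -0.80 for Bglap2 and -0.89 for Chad. With all 9 arrays none of these genes passed.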
